A study of Zea mays with 12 samples.

How the data were processed

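The series holds 12 RNA-seq libraries from roots of maize (*Zea mays*), in 4 groups of 3. Per the labels, the groups are an untreated control, plants given all of their nitrogen treatment as urea (urea), plants given equal parts of urea and of a source labelled only as nitrogen (urea+N), and plants given that source alone (N). The series title names urea and ammonium, while the sample labels do not name the chemical form of N. Per the labels' protocols, roots of 4 plants were pooled for each sample, total RNA was extracted from powdered tissue, and libraries were made with an Illumina kit from 2 µg of RNA. The labels do not say whether the pools of a group were grown separately, so the p-values measure the spread between these samples, part of which may be technical.

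Reads were aligned with HISAT2 to the maize genome build B73 RefGen_v4, per the submitters' processing notes, which also name Cuffdiff, whose output was not used here. Per the file headers, StringTie 1.3.4d estimated the abundance of the transcripts of the annotation AGPv4.37 in each library separately, without assembling others. The deposited file of each library lists 138333 transcripts of 46335 genes, with TPM (transcripts per 1000000 transcripts), FPKM and mean read coverage for each transcript. The deposited TPM values sum to 1000000 in each library, so a TPM is a share of the library and not an amount per cell. These values are not counts. Read counts were not estimated from the coverage, so no test on counts was run. The ratio of coverage to FPKM is constant within a file and gives the aligned bases of the library. The strand setting is not given in the sources used here, so reads of a gene and of an overlapping gene on the other strand cannot be told apart.

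TPM was summed over the transcripts of each gene. Genes with at least 1 TPM in at least 3 of the 12 libraries were tested, which left 25731 genes. Differences were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of variance on mean expression), as a model of the 4 group means over all 12 libraries with 8 residual degrees of freedom and no further scaling. Tests of genes and gene groups are two-sided, p-values of genes were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Errors beside TPM values are SDs over 3 libraries, and errors beside log2 fold changes are SEs from the model. Each fed group was compared with the control, the fed groups were compared with each other, and urea+N was compared with the mean of urea and N on the log2 scale. Tables were handled with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.

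The design, the settings to be tried and the rule for the genes named in the text were fixed before the data were examined. The rule takes, for each comparison, the called genes that have a name, whose 3 values in one group all lie above the 3 in the other and whose higher group mean is at least 5 TPM, and of these the 8 with the largest rise and the 8 with the largest fall against the control (5 and 5 between fed groups), plus up to 3 called members of each gene list. Genes without a name are counted, with at most 2 identifiers per direction. Not all named genes so taken are described. The text leaves out *FDX3* in urea, and zma-MIR171f, *RAD51B* and the call of *CAB1* in urea+N. It also leaves out *ITPK1*, *BIPE2*, *H3C2* at Zm00001d036250 and the call of *NIP2-2* in N, and *Zlp* in urea+N and N. Each of these calls was lost on leaving out some single compared library. The files pair few genes with names. Of the 46335 genes, 221 have a gene name and 154 are microRNA genes, and 148 of the named genes were tested. None of the 44146 identifiers of the Zm00001d type was found in the RefSeq table, which belongs to the assembly Zm-B73-REFERENCE-NAM-5.0 and was used for names only. Of 184 distinct names of nuclear genes, 175 were found in it as a symbol or synonym. All coordinates are those of B73 RefGen_v4 in the deposited files.

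The 28 gene lists fixed before the data were examined, which cover nitrogen transport and assimilation among others, match at most 1 gene each by name and could not be tested. The list of flavonoid synthesis matches *C2* and that of photosynthetic cells *CAB1*. The lists without a match include the lists for urea and ammonium transport, nitrate transport and reduction and glutamine and asparagine metabolism, whose members are not analysed here by name. In their place, 20 groups were made from the names in the files after those names were seen and before any comparison was made. They cover aquaporins; histones H3 and H4 with the replication clamp; cytosolic ribosomal proteins and translation factors; photosynthesis genes of green cells; defence and specialised metabolism; meristem and root patterning regulators; cell number regulators; the cytoskeleton; chaperones; sugar and ferredoxin metabolism; nitrogen, sulfur and vitamin metabolism; hormone conjugation and signalling; chromatin and gene silencing; nutrient-responsive microRNA precursors; all microRNA precursors; kernel genes; beta-expansins and a polygalacturonase of pollen type; plastid-encoded genes; mitochondrion-encoded genes; and ribosomal RNA. The 16 groups with at least 3 tested members were tested against the other genes with camera of limma at a preset inter-gene correlation of 0.01. Its p-values were adjusted over the 16 groups within each comparison, and it was run again with an estimated correlation. Camera looks for a shift in one direction, so members that rise and members that fall can cancel out. The test fry of limma, planned beside camera for the gene lists, was run as well. It does not set a group against the other genes. The mixed form of fry counts changes in either direction, and its p-values are unadjusted. The histone genes H3C2 and H4C7 have many near-identical copies whose reads can be assigned to a wrong copy, so their single-gene values are uncertain. The group test takes these copies as separate members.

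Comparisons with the same 3 control libraries share their chance values. Overlaps of calls are given beside the overlap of independent lists and beside 100 simulations of unchanged groups against shared controls. The 3 controls cannot be split into parts of at least 2 libraries each. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, a minimum of 5 TPM, median-of-ratios scaling, only the compared groups in the model, the replicate number as a block, array weights, FPKM in place of TPM, a fold of at least 2, and leaving out each library in turn. Leaving out the library urea+N 3 from comparisons of other groups was added after the data were seen.

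The test was tested on simulated data with 200 changed genes among 25731. For N against control, 8% of genes changed 1.25-fold, 34% of those changed 1.5-fold, 74% of those changed 2-fold and 96% of those changed 4-fold were recovered, and 8 of the 114 genes called were false. For urea against N the shares were 4%, 30%, 68% and 92%, and 7 of the 104 genes called were false.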

Results

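The roots of maize plants fed with urea, with a nitrogen source labelled N, or with equal parts of both were compared with roots of control plants, with 3 libraries per group. Gene expression was given as TPM, the number of transcripts of a gene per 1000000 transcripts of the library. Aligned sequence was 2.02, 1.78 and 1.79 gigabases in the control libraries, 1.85, 1.87 and 1.83 in urea, 1.94, 2.21 and 2.01 in urea+N and 1.97, 1.86 and 1.95 in N. Of 46335 annotated genes, 29289 to 29521 were listed above 0 TPM in 11 of the libraries, and 25806 in the library urea+N 3. In urea+N 3, 307 genes were listed at 0 that exceeded 1 TPM in each of the other libraries, against 2 to 10 such genes in each other library. Pearson correlations of log2(TPM + 1) across genes within a group were 0.973 to 0.980 without urea+N 3, with 0.954 as the lowest with it. The first principal component held 27.6% of the variance and the second 18.2%. The library urea+N 3 stood apart, with a score of 54.8 on the first and 65.4 on the second component, against -51.4 to 17.5 and -19.7 to 22.0 in the other libraries. No pair of libraries shared more than 1.01% of identical TPM values, and each was kept as a separate sample.

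**Figure D1:**
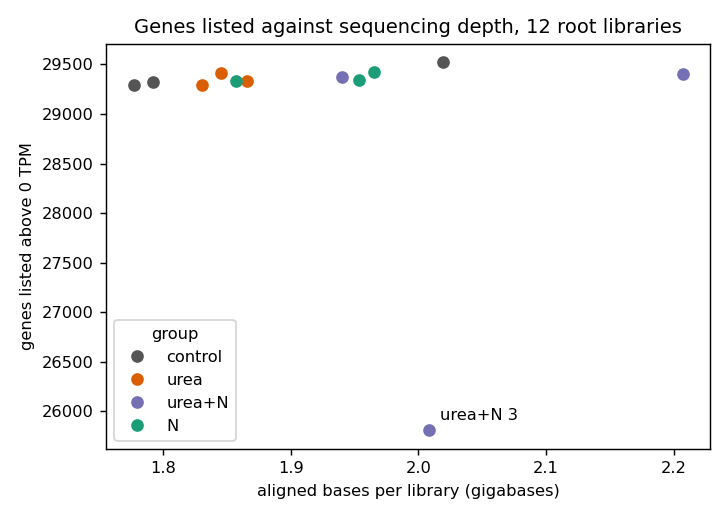
Genes listed above 0 TPM (vertical axis) against aligned gigabases (horizontal axis) for the 12 libraries, coloured by group. The library urea+N 3 lists 25806 genes, while the others list 29289 to 29521.

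Urea-fed roots were first compared with control roots. The largest fall among the named genes was that of *C2* (Zm00001d052673, chromosome 4, 196893203 to 196896534), which encodes chalcone synthase, the entry enzyme of flavonoid synthesis. Its level went from 106 ± 24.4 TPM in control to 39.8 ± 3.49 TPM in urea (SD, n = 3), a log2 fold change of -1.37 ± 0.15 (SE, limma, adjusted p = 0.000391). *CNR2* (Zm00001d050899, chromosome 4, 129065452 to 129066520), a cell number regulator, fell from 85.8 ± 9.90 to 50.6 ± 10.5 TPM, and *GST4* (Zm00001d024839, chromosome 10, 90384434 to 90385822), a glutathione transferase, fell from 471 ± 40.2 to 316 ± 46.2 TPM, with log2 fold changes of -0.76 and -0.58. *RBCS* (Zm00001d052595, chromosome 4, 194257728 to 194258862), the small subunit of Rubisco, rose from 10.5 ± 3.43 to 25.2 ± 4.63 TPM (log2 fold change 1.22 ± 0.23, adjusted p = 0.0106).

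Aquaporins, which are channels for water and small solutes, formed the one gene group that passed its test in this comparison. Of 18 tested members, 4 rose and 0 fell. The group had an adjusted p of 0.00368 at the preset correlation, 0.716 with an estimated correlation and 0.196 with fry. The tonoplast aquaporin *TIP1-1* (Zm00001d027652, chromosome 1, 10150836 to 10152891) rose from 2355 ± 205 to 3349 ± 195 TPM, a log2 fold change of 0.51 ± 0.09 (adjusted p = 0.00598). The plasma membrane aquaporin *PIP2-6* (Zm00001d019565, chromosome 7, 43071903 to 43073370) rose from 1009 ± 58.7 to 1367 ± 54.8 TPM, and *PIP2-3* (Zm00001d051174, chromosome 4, 147173978 to 147176860) from 459 ± 36.4 to 611 ± 18.8 TPM. The fourth, *PIP2-4* (Zm00001d017288, chromosome 5, 191817119 to 191819914), had 1233.6 ± 101 TPM in control and 1535 ± 64.5 TPM in urea, and its adjusted p of 0.0297 became 0.0536 without control 1, 0.1003 without control 2, 0.0873 without urea 1 and 0.103 without urea 2. The call of *PIP2-4* also ended with no filter, with FPKM and with only the compared groups in the model. The summed TPM of the group was 18324 to 20844 in the control libraries and 21682 to 22687 in the urea libraries.

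Defence and specialised metabolism had 2 members higher and 2 lower of 6 tested in urea, and the group did not pass its test (adjusted p = 0.998). Camera tests for a shift in one direction, and the mixed form of fry gave an unadjusted p of 6.66e-05. That form gave 5.82e-05 for aquaporins. It does not set a group against other genes, and 20.1% of all genes tested had an unadjusted p under 0.05 by limma. *BX6* (Zm00001d048634, chromosome 4, 1846585 to 1848071), an oxygenase of benzoxazinoid synthesis, rose from 34.6 ± 2.68 to 49.0 ± 3.83 TPM (log2 fold change 0.49 ± 0.08). *SAMDC* (Zm00001d003157, chromosome 2, 33981493 to 33984783), which encodes S-adenosylmethionine decarboxylase of polyamine synthesis, rose from 793 ± 34.02 to 1007 ± 52.1 TPM (log2 fold change 0.34 ± 0.06). *IDI2* (Zm00001d049042, chromosome 4, 13682555 to 13688155), of the methionine salvage cycle, had a log2 fold change of -0.58 ± 0.12 (adjusted p = 0.0154), with an adjusted p of 0.0529 without control 2 and 0.0527 without urea 3. *LA1* (Zm00001d049174, chromosome 4, 19153020 to 19159545), a regulator of shoot gravitropism, had one of 0.59 ± 0.12 (adjusted p = 0.0124), with an adjusted p of 0.0522 without control 2. Restricting the model to the compared groups ended the calls of *IDI2* and *LA1*, with adjusted p of 0.0707 and 0.0598.

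Of the 25731 genes tested, 1638 were called in urea against control, 639 higher and 999 lower, and 15 of 148 named genes were among them. Under median-of-ratios scaling 805 were higher and 770 lower, which shifts the share of higher calls from 39.01% to 51.1%. The count was 1056 without control 2, 901 without control 3 and 910 without urea 2. The genes whose 3 values in one group were all above those in the other made up 27.9% of the genes, where chance gives 10%. Among genes without a name, Zm00001d047736 (chromosome 9, 140319258 to 140322843) rose from 17.0 ± 2.80 to 448 ± 34.8 TPM, with a log2 fold change of 4.65 ± 0.14. Zm00001d049466 (chromosome 4, 31334396 to 31335175) was at 5.17, 6.08 and 6.86 TPM in the control libraries and was listed at 0 in the 3 urea libraries.

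Roots fed with both sources, urea+N, were compared with control roots next. *C2* fell to 21.5 ± 3.39 TPM, a log2 fold change of -2.24 ± 0.15 (adjusted p = 5.87e-06). *IDI2* fell from 242 ± 49.6 to 124 ± 9.54 TPM (log2 fold change -0.94 ± 0.12), and *CNR2* fell to 52.4 ± 6.09 TPM. *PSAH* (Zm00001d038984, chromosome 6, 168207284 to 168208191), a subunit of photosystem I, rose from 1.34 ± 0.443 to 8.84 ± 3.52 TPM (log2 fold change 2.03 ± 0.43, adjusted p = 0.0102), and *RBCS* rose to 28.4 ± 6.00 TPM. *CISZOG2* (Zm00001d012335, chromosome 8, 172652749 to 172654298), which encodes a cis-zeatin O-glucosyltransferase of cytokinin conjugation, rose from 8.74 ± 1.497 to 18.2 ± 1.04 TPM (log2 fold change 0.99 ± 0.13, adjusted p = 0.000566).

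*LA1* rose from 23.4 ± 3.21 to 43.0 ± 1.14 TPM and *BX6* to 56.3 ± 3.05 TPM, with log2 fold changes of 0.86 and 0.69. *TIP1-1* rose to 3625 ± 372 TPM, *PIP2-6* to 1425 ± 36.1 TPM and *SAMDC* to 1113 ± 38.7 TPM. *PHI1* (Zm00001d034256, chromosome 1, 288168990 to 288176921), which encodes glucose-6-phosphate isomerase of glycolysis, rose from 152 ± 14.3 to 199 ± 2.94 TPM. Of the 18 aquaporins tested, 3 rose and 1 fell, and the group did not pass its test (adjusted p = 0.126). The aquaporin that fell was *NIP2-2* (Zm00001d037228, chromosome 6, 116839545 to 116843339), of the family that includes silicon channels, at 10.6 ± 2.36 TPM in control and 6.98 ± 0.649 TPM in urea+N (adjusted p = 0.0312). Its adjusted p was 0.0963 without control 1, 0.0796 without control 3, 0.0931 without urea+N 2 and 0.0531 without urea+N 3, 0.0538 under median-of-ratios scaling and 0.127 with only the compared groups in the model.

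None of the 16 groups tested passed in urea+N against control with camera at the preset correlation. With fry, which does not set a group against other genes, nutrient-responsive microRNA precursors had an adjusted p of 0.0150. By the same test it was 0.0258 for the photosynthesis group, for meristem and root patterning regulators and for the cytoskeleton. In the microRNA group, zma-MIR169e and zma-MIR169h had near-identical TPM and may not be separate measurements. Without urea+N 3, histones H3 and H4 with the replication clamp (adjusted p = 0.0415) and ribosomal RNA (adjusted p = 0.0289) were lower than other genes at the preset correlation. With an estimated correlation and without urea+N 3 their adjusted p was 0.786 and 0.872. In this comparison 3594 genes were called, 1395 higher and 2199 lower, with 31 named genes among them. The higher genes were 38.8% of the calls, and 51.3% under median-of-ratios scaling, where 1721 were higher and 1632 lower. The count was 2330 without control 3, 3236 without urea+N 3, and 1880 with only the compared groups in the model. The groups were fully separated at 30.7% of genes. Zm00001d035214 (chromosome 6, 10070049 to 10071716) was at 0.182 to 1.097 TPM in the control libraries and at 54.3 to 62.6 TPM in the urea+N libraries, a log2 fold change of 5.35 ± 0.23. Zm00001d020342 (chromosome 7, 107669735 to 107670934) went from 17.7 ± 2.01 TPM in control to 0.399 ± 0.0713 TPM in urea+N, and was at 10.8, 0.222 and 15.9 TPM in the N libraries.

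In N-fed roots against control roots, *C2* fell to 29.9 ± 2.099 TPM (log2 fold change -1.77 ± 0.15, adjusted p = 3.46e-05), *IDI2* to 154 ± 7.58 TPM and *GST4* to 304 ± 11.2 TPM. *PSAH* rose to 10.8 ± 5.78 TPM and *RBCS* to 28.9 ± 5.71 TPM, with log2 fold changes of 2.203 and 1.40. *CISZOG2* rose to 18.8 ± 2.96 TPM (log2 fold change 1.02 ± 0.13) and *PHI1* to 199 ± 10.1 TPM. The benzoxazinoid gene *BX6* rose to 55.4 ± 1.80 TPM, and *GLU1* (Zm00001d023994, chromosome 10, 35174831 to 35179918), a beta-glucosidase that releases benzoxazinoids from their glucosides, rose from 1379 ± 116 to 2007 ± 80.3 TPM (log2 fold change 0.54 ± 0.09, adjusted p = 0.00203). *LA1*, *TIP1-1*, *PIP2-6* and *SAMDC* rose as well, to 37.8 ± 3.48, 3605 ± 138, 1437 ± 134 and 1136 ± 4.68 TPM.

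The group of 24 histone H3, histone H4 and replication clamp genes was lower than other genes in N, with 5 members lower and 0 higher (adjusted p = 0.000230), and had an adjusted p of 0.589 with an estimated correlation. The member *H3C2* at Zm00001d039790 (chromosome 3, 14754274 to 14754684) went from 179 ± 4.24 to 145 ± 6.21 TPM (adjusted p = 0.00670). The photosynthesis group had 2 members higher and 0 lower of 6 tested, with an adjusted p of 0.0705, and 0.0329 with no filter, and with the filter had an adjusted p of 0.444 with an estimated correlation. Aquaporins had 2 higher and 1 lower of 18 (adjusted p = 0.0767), and cytosolic ribosomal proteins and translation factors 0 higher and 1 lower of 12 (adjusted p = 0.114). Defence and specialised metabolism had 3 higher and 2 lower of 6 (adjusted p = 0.878). Adjusted p-values of camera were 0.218 for the cytoskeleton and for nutrient-responsive microRNA precursors, and 0.316 for nitrogen, sulfur and vitamin metabolism. They were 0.362 for meristem and root patterning regulators, 0.867 for chromatin and gene silencing and 0.979 for cell number regulators. For chaperones and for sugar and ferredoxin metabolism they were 0.878. The mixed form of fry gave an unadjusted p of 1.41e-05 for defence and specialised metabolism, 1.40e-05 for the histone group and 3.06e-06 for aquaporins. For nitrogen, sulfur and vitamin metabolism it gave 2.24e-06. Fry does not set a group against other genes, and 25.9% of all genes tested had an unadjusted p under 0.05 by limma. Small values of the mixed form are thus not particular to these groups. In its directional form, fry gave an adjusted p of 0.0184 for the histone group and for the photosynthesis group. For the cytoskeleton it gave 0.0380.

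In N against control 3287 genes were called, 1447 higher and 1840 lower, with 29 named genes among them. Under median-of-ratios scaling 1687 were higher and 1488 lower. The count was 2110 without control 3, 2079 without N 1 and 1962 without N 3. The groups were fully separated at 34.8% of genes. Zm00001d043442 (chromosome 3, 200059008 to 200062529) fell from 126 ± 27.9 to 10.4 ± 1.39 TPM, a log2 fold change of -3.46 ± 0.20. Zm00001d043427 (chromosome 3, 199485601 to 199485861) was at 0.503 TPM in control 2, was listed at 0 in the other 2 control libraries, and was at 53.7 to 75.4 TPM in the N libraries.

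**Figure D2:**
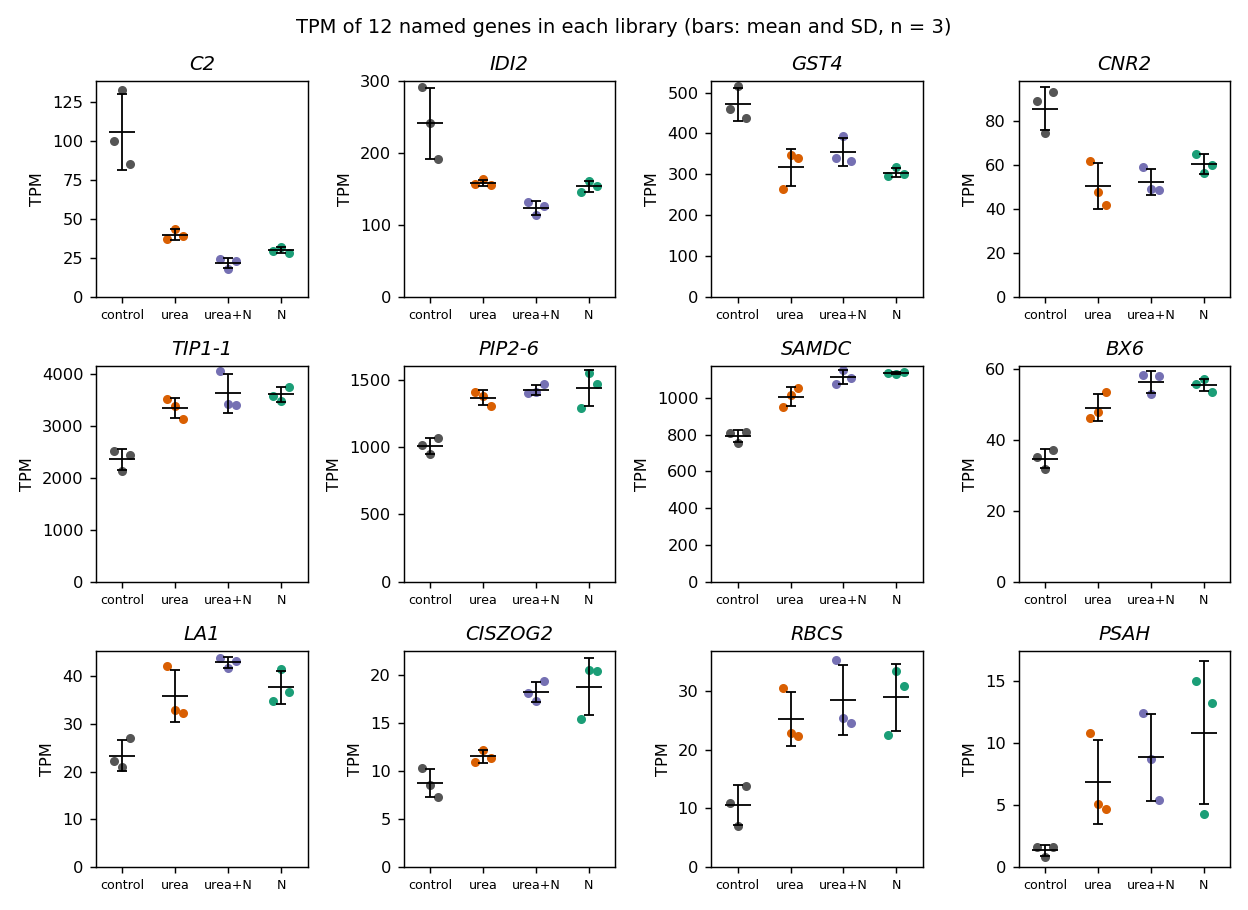
TPM (vertical axis) of 12 named genes in the libraries of the 4 groups (horizontal axis), with bars for the mean and SD of 3 libraries. *C2* is at 106 TPM in control and at 21.5 to 39.8 TPM in the fed groups, and *RBCS* is at 10.5 TPM in control and at 25.2 to 28.9 TPM in them.

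The 3 comparisons with control were then set side by side. Of 4559 genes called in at least 1 of them, 1332 were called in all 3, 572 higher and 760 lower, and 12 named genes were among them. These were *C2*, *IDI2*, *GST4* and *CNR2*, which were lower, and *RBCS*, *PSAH*, *LA1*, *BX6*, *TIP1-1*, *PIP2-6*, *SAMDC* and *GLU1*, which were higher. The count of 1332 was 879 without control 2, 773 without control 3 and 819 without urea 2. For single comparisons some of the named calls depended on the libraries. The call of *PSAH* in urea (adjusted p = 0.0424) was lost without any 1 of the 6 libraries compared, with adjusted p of 0.0637 to 0.134, and with no filter or with FPKM. That of *GLU1* in urea (adjusted p = 0.0477) was lost without control 2, control 3, urea 2 or urea 3, with adjusted p of 0.112 to 0.175, without urea+N 3 (0.0505), and with no filter, with FPKM or with only the compared groups. In urea+N, the adjusted p of *GLU1* was 0.0253, and 0.0650 without control 2, 0.0964 without control 3, 0.0634 without urea+N 1 and 0.0714 without urea+N 3. The adjusted p of *GST4* in urea+N was 0.0278, 0.0574 under median-of-ratios scaling, and 0.0568 without control 1, 0.101 without control 2, 0.0750 without urea+N 1 and 0.0813 without urea+N 3. That of *CNR2* in N was 0.0414, and 0.108 without control 1, 0.141 without control 3, 0.0668 without N 1, 0.122 without N 2 and 0.112 without N 3. No filter also ended the calls of *GLU1* in urea+N and of *CNR2* in N, and only the compared groups that of *GLU1* in urea+N.

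Urea and urea+N shared 597 higher and 850 lower calls, where independent lists would share 34.6 and 85.4 and simulated unchanged groups share 0. Urea and N shared 593 higher and 816 lower calls, against 35.9 and 71.4 for independent lists and 0 simulated, and 1 gene was called in opposite directions. Urea+N and N shared 1079 higher and 1356 lower calls, against 78.4 and 157 for independent lists and 0.01 simulated. Correlations of log2 fold changes across genes were 0.76, 0.79 and 0.80 for these pairs, and 0.50 in each simulation. The covariances exceeded the simulated ones by 0.105, 0.101 and 0.136. For the shared calls, part of the excess over independent lists may come from the shared controls, which are too few to be split, and genes are not independent replicates. The simulated groups hold no effect, so almost no gene is called in them. Their shared counts near 0 thus do not show how much overlap the shared controls add where many genes are called.

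**Figure D3:**
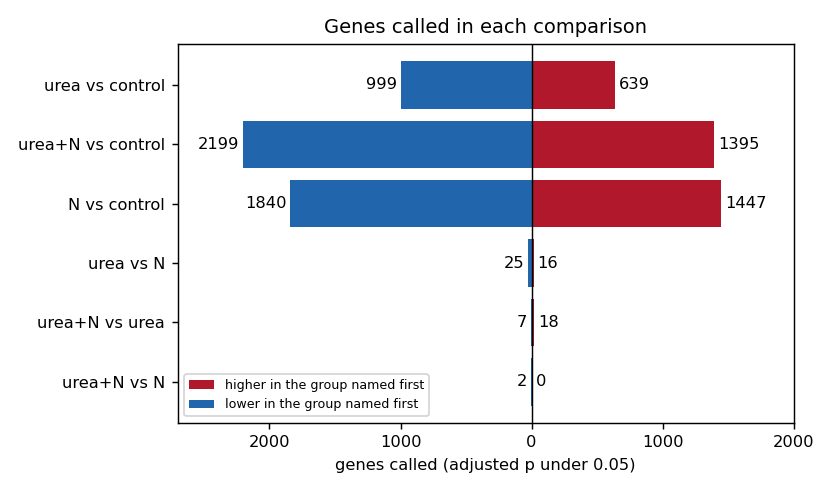
Number of genes called (horizontal axis) in each of the 6 pairwise comparisons (vertical axis), with bars to the right for genes higher and to the left for genes lower in the group named first. The comparisons with control give 1638, 3594 and 3287 genes, and those between fed groups 41, 25 and 2.

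Urea was compared directly with N to see where the sources differed. With limma, 0 of the 148 named genes tested were called, and 28 had an unadjusted p under 0.05. The 95% intervals of the log2 difference, urea minus N, were -0.70 to 0.33 for *RBCS*, -0.301 to 0.09 for *TIP1-1*, -0.19 to 0.29 for *GST4* and -0.34 to 0.18 for *LA1*. *C2* was at 39.8 ± 3.49 TPM in urea and 29.9 ± 2.099 TPM in N (log2 difference 0.40, adjusted p = 0.459), and *CISZOG2* at 11.5 ± 0.658 and 18.8 ± 2.96 TPM (log2 difference -0.65, 95% interval -0.94 to -0.36, adjusted p = 0.109). Histones H3 and H4 with the replication clamp were higher in urea than in N as a group relative to other genes, with 0 of 24 members called and 7 at an unadjusted p under 0.05 (adjusted p = 5.64e-08 for the group), and had an adjusted p of 0.328 with an estimated correlation. The summed TPM of this group overlapped, at 7291 to 7965 in the urea libraries and 7045 to 7370 in the N libraries. Ribosomal proteins and translation factors (adjusted p = 0.00700) and the cytoskeleton genes (adjusted p = 0.0293) lay in the same direction, with 0 members called and 4 of 12 and 0 of 6 at an unadjusted p under 0.05. With an estimated correlation they had adjusted p of 0.539 and 0.328. The adjusted p for the cytoskeleton was 0.0509 without urea+N 3.

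Of 25731 genes, 41 were called between urea and N, 16 higher and 25 lower in urea. Zm00001d014976 (chromosome 5, 70820654 to 70822222) was at 6.54 ± 0.810 TPM in urea and 0.539 ± 0.214 TPM in N, with 9.08 ± 2.16 TPM in control. The count was 115 without urea 1, 3 without urea 2, 1 without urea 3, 15 without N 1, 23 without N 2 and 4 without N 3, and 4 with only the compared groups in the model.

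A score of the response was made for each library as the mean log2 change from control over the genes called in urea+N against control, each signed by its direction in urea+N. It was 0.528 ± 0.0456 in urea and 0.675 ± 0.0231 in N (SD, n = 3), a difference of -0.147 for urea minus N, and every urea library lay below every N library. The exact permutation test gave a two-sided p of 0.1, the smallest that 3 libraries against 3 allow. Without urea+N 3 the scores were 0.561 and 0.721, with a difference of -0.160. The control libraries that set the zero of the score also helped to choose and sign the genes, so their chance values add to both scores, and the difference does not depend on that zero.

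**Figure D4:**
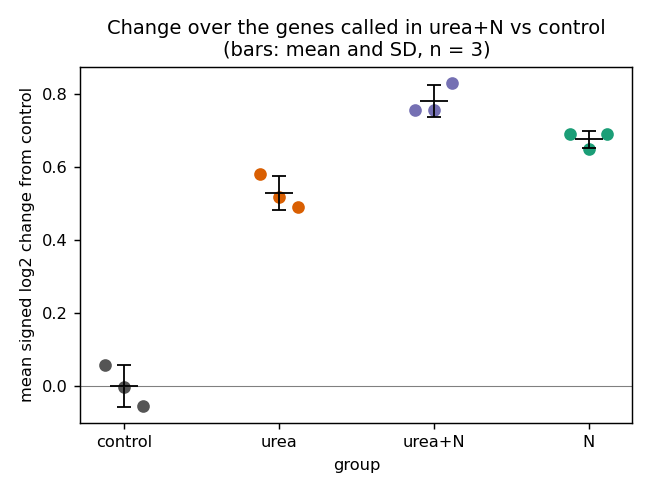
Mean signed log2 change from control (vertical axis) over the genes called in urea+N against control, for each library of the 4 groups (horizontal axis), with bars for the mean and SD of 3 libraries. The mean is 0.528 in urea and 0.675 in N, and urea+N, whose calls chose the genes, lies higher by construction.

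The mixture was compared with each source alone. Against urea, 25 genes were called, 18 higher and 7 lower in urea+N. With limma, 0 of the 148 named genes were among them, and 12 had an unadjusted p under 0.05. *C2* was at 21.5 ± 3.39 TPM in urea+N and 39.8 ± 3.49 TPM in urea (adjusted p = 0.0790), and *CISZOG2* at 18.2 ± 1.04 and 11.5 ± 0.658 TPM (adjusted p = 0.151). No gene group passed its test here (lowest adjusted p = 0.511, for the cytoskeleton), although histones H3 and H4 with the replication clamp were lower in urea+N without urea+N 3 at the preset correlation (adjusted p = 0.00799). With an estimated correlation and without urea+N 3 their adjusted p was 0.789. Zm00001d043344 (chromosome 3, 197152506 to 197154049) was at 0.260 to 2.18 TPM in the urea libraries and 16.9 to 24.8 TPM in the urea+N libraries, a log2 fold change of 3.23 ± 0.34. Its adjusted p of 0.00871 was 0.0719 with a pseudocount of 0.1 and 0.0971 with only the compared groups. The count was 112 without urea 1, 4 without urea 2, 2 without urea 3 and 12 without urea+N 3, and 3 with only the compared groups.

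Against N, 2 genes were called in urea+N, both lower, and against the mean of urea and N the same 2. Zm00001d043329 (chromosome 3, 196701801 to 196708211) was at 17.0 ± 5.82 TPM in urea+N and at 48.8 ± 0.974 TPM in urea, 53.4 ± 4.60 TPM in N and 53.6 ± 2.12 TPM in control. Zm00001d028193 (chromosome 1, 25916570 to 25919479) was at 21.8 ± 0.737 TPM in urea+N, 33.3 ± 1.34 TPM in urea, 37.4 ± 1.499 TPM in N and 34.7 ± 2.68 TPM in control. At an unadjusted p under 0.05 there were 1952 genes in urea+N against N and 2306 against the mean. Histones H3 and H4 with the replication clamp were higher in urea+N than in N relative to other genes, with 0 of 24 called and 2 at an unadjusted p under 0.05 (adjusted p = 0.000128 for the group), an adjusted p of 0.845 with an estimated correlation and of 0.0983 without urea+N 3. Ribosomal RNA genes, which did not pass here (adjusted p = 0.490), were lower without urea+N 3 (adjusted p = 0.0119, and 0.0128 against the mean) at the preset correlation. With an estimated correlation and without urea+N 3 their adjusted p was 0.976 and 0.975.

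The counts of the mixture against N and against the mean rested on single libraries. Against N the count was 7 without urea+N 1, 3 without urea+N 3, 0 without N 1, 5 without N 2 and 0 without N 3. Against the mean it was 1 without urea 1, 1 without urea 3, 25 without urea+N 1, 4 without urea+N 2, 5 without urea+N 3, 5 without N 2 and 1 without N 3. The call of Zm00001d043329 against N was lost without urea+N 2, N 1, N 2 or N 3, with adjusted p of 0.0594 to 0.244, and that of Zm00001d028193 without N 1 or N 3, with adjusted p of 0.110 and 0.0787. Both were also lost with only the compared groups in the model.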

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

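Of the tests in this part, that of urea against N without urea+N 3 was chosen after the result was seen. The results below are those where a test of the difference itself set the effects of 2 fed groups apart. For urea against N 41 genes differed. The log2 differences of the genes singled out were 2.30 for Zm00001d014976, 1.57 for Zm00001d017375, -2.63 for Zm00001d043344 and -1.79 for Zm00001d015133. The call of Zm00001d014976 held without any single library compared. That of Zm00001d017375 was lost without urea 2, urea 3 or N 3 (adjusted p = 0.0652, 0.0828 and 0.0689). For Zm00001d043344 it was lost without urea 2, urea 3, N 2 or N 3 (0.0530, 0.0520, 0.0566 and 0.0788), and for Zm00001d015133 without urea 1, urea 2, urea 3, N 2 or N 3 (0.0733, 0.135, 0.181, 0.0969 and 0.225). With only the compared groups in the model the calls of Zm00001d017375 (0.0649), Zm00001d043344 (0.121) and Zm00001d015133 (0.182) ended. A pseudocount of 0.1 ended those of Zm00001d043344 (0.120) and Zm00001d015133 (0.0518). That of Zm00001d015133 was also lost with no filter (0.0747), under median-of-ratios scaling (0.0514), with FPKM (0.0535) and without urea+N 3 (0.0527).

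For urea+N against urea 25 genes differed. The log2 differences were 3.23 for Zm00001d043344, 1.31 for Zm00001d012333, -1.55 for Zm00001d051773 and -1.52 for Zm00001d043329. The call of Zm00001d043344 held without any single library compared and was lost with a pseudocount of 0.1 (adjusted p = 0.0719). That of Zm00001d012333 was lost without urea 2, urea 3, urea+N 2 or urea+N 3 (adjusted p = 0.104, 0.134, 0.0661 and 0.0716), that of Zm00001d051773 without urea 2, urea 3, urea+N 1, urea+N 2 or urea+N 3 (0.240, 0.228, 0.0860, 0.107 and 0.0590), and that of Zm00001d043329 without urea 2 or urea 3 (0.104 and 0.118). With only the compared groups in the model the calls of all 4 ended (0.0971, 0.0967, 0.182 and 0.223). That of Zm00001d051773 was also lost with a pseudocount of 0.1 (0.0537), no filter (0.0875), median-of-ratios scaling (0.0505) and FPKM (0.0527). Zm00001d012333 is at chromosome 8, 172624862 to 172626394, near *CISZOG2*, and both were at higher TPM in urea+N and N than in urea, although the difference of *CISZOG2* was not called.

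For urea+N against N 2 genes differed, with log2 differences of -1.65 for Zm00001d043329 and -0.75 for Zm00001d028193, and for urea+N against the mean of urea and N the same 2 genes. In the urea+N libraries Zm00001d043329 was at 21.7, 18.9 and 10.5 TPM, and in the other 9 libraries at 48.0 to 56.2 TPM.

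Splits of the libraries of each comparison into other groups of the same size gave the following counts. For urea against N the real split called 41 genes and the highest other split 3; for urea+N against urea they called 25 and 4; and for urea+N against N 2 and 7, where 6 of the 10 splits called at least as many as the real one. The real splits against control called 1638, 3594 and 3287 genes and the highest other splits 3, 4 and 2. With 10 splits, of which the real one is 1, there are too few for a share under 0.05. In the other splits each group mixes libraries of both real groups, so a real difference widens the spread and lowers the count. Their low counts are thus not those to be had without any difference, and no conclusion is drawn from the contrast. For urea+N against the mean of urea and N, 54 of 100 splits of the 9 libraries gave at least 2 genes, the highest other 27, so chance was not excluded. Groups of 3 were not tested for outlying samples.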

How the results depend on the processing

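Leaving urea+N 3 out of comparisons of other groups, and the gene groups with all of their settings, were chosen after the data were seen; all other alternatives were planned. Of the 102 called results for single genes, 55 kept their call under every setting other than the 2-fold threshold and the left-out libraries, and 0 reversed direction. Of these results, 12 of 21 in urea against control, 17 of 37 in urea+N against control and 20 of 34 in N against control kept their call without any single compared library, as did 1 of 4 in urea against N, 1 of 4 in urea+N against urea and 0 of 2 in urea+N against N. Counts against control stayed within 1.5 times the reported count under the pseudocount, both filters, median-of-ratios scaling and FPKM. Depth was 1.78 to 2.21 gigabases, and its effect on the calls was not tested. In simulated data with 200 changed genes among all genes tested, 34% of 1.5-fold changes in N against control were recovered. Only 114 genes were called there, against 3287 in the data, so the cut-off on the unadjusted p was stricter in the simulation. The share recovered in the data may therefore differ.

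A fold of at least 2 left 382 (urea), 805 (urea+N) and 692 (N) genes against control, 13 in urea against N, 6 in urea+N against urea, 1 in urea+N against N and 1 against the mean, by construction. Array weights, which gave urea+N 3 a weight of 0.215, raised the counts to 2594 in urea against control, 354 in urea against N, 108 in urea+N against urea and 6 against the mean. With only the compared groups in the model there were 1880 in urea+N against control, 4 in urea against N, 3 in urea+N against urea, 1 in urea+N against N and 1 against the mean, with fewer residual degrees of freedom. A pseudocount of 0.1 gave 5 in urea+N against N and 5 against the mean, no filter gave 6 in urea+N against N, and a minimum of 5 TPM gave 4 against the mean; the cause was not tested.

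The replicate numbers did not pair the libraries. Same-numbered libraries had residual correlations of -0.043 to 0.065, with 0 of 18 pairs over 0.1, and 5 of 12 libraries correlated best with their own number. The replicate block gave 1465, 3241 and 2975 genes against control, 24 in urea against N, 7 in urea+N against urea, 0 in urea+N against N and 0 against the mean (2571, 1937 and 2300 in the last 3 at an unadjusted p under 0.05). Calls that ended under the block included *PIP2-4* (adjusted p = 0.0571) and *GLU1* (0.0868) in urea, Zm00001d043344 in urea against N (0.0610), Zm00001d012333 (0.0625), Zm00001d051773 (0.0596) and Zm00001d043329 (0.0516) in urea+N against urea, and Zm00001d043329 (0.122) and Zm00001d028193 (0.104) in urea+N against N.

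Without 1 compared library at a time, counts ranged from 901 to 1365 (urea), 2330 to 3236 (urea+N) and 1962 to 2708 (N) against control, 1 to 115 in urea against N, 2 to 112 in urea+N against urea, 0 to 7 in urea+N against N and 1 to 25 against the mean, and the genes called in all 3 comparisons with control from 773 to 1572. Without urea+N 3 there were 2111 in urea and 4122 in N against control and 46 in urea against N.

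The group calls ended with an estimated correlation, with all libraries and without urea+N 3: aquaporins in urea (adjusted p = 0.716 and 0.913), histones in N (0.589 and 0.538), in urea against N (0.328 and 0.556) and in urea+N against N (0.845 and 0.976), and in urea against N ribosomal proteins (0.539 and 0.650) and cytoskeleton (0.328 and 0.556). With no filter, nutrient-responsive microRNA precursors in urea+N (0.0350) and photosynthesis genes in N (0.0329) passed. Without urea+N 3, at the preset correlation only, histones passed in urea+N against control (0.0415) and urea (0.00799) and ended against N (0.0983), ribosomal RNA passed in urea+N against control (0.0289), N (0.0119) and the mean (0.0128), and the cytoskeleton ended in urea against N (0.0509). The cause was not tested.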

Other observations

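In this part, the test of the urea+N treatment as the source of the missing genes, the test for shoot tissue and the excess over the other libraries were chosen only after the result was seen.

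MicroRNA precursors were listed for 154 genes, of which 30 were tested. In urea against control 2 were lower and 0 higher, in urea+N 2 lower and 0 higher, and in N 1 lower and 0 higher, and the group did not pass its test (adjusted p = 0.985, 0.975 and 0.878). The precursor zma-MIR168a, of the family that targets an ARGONAUTE transcript, was at 33.1, 43.0 and 42.6 TPM in the control libraries, at 21.9 to 24.7 TPM in urea, 23.6 to 29.7 TPM in urea+N and 21.1 to 33.3 TPM in N, with log2 fold changes of -0.73, -0.58 and -0.54 (limma, adjusted p = 0.0179, 0.0302 and 0.0455). Each of these calls was lost without control 2 or control 3: adjusted p was 0.0707 and 0.0771 in urea, 0.101 and 0.104 in urea+N, and 0.143 and 0.145 in N. They were also lost without urea 1 or urea 2 (0.0510 and 0.0741), without urea+N 1 or urea+N 2 (0.0757 and 0.0904) and without N 1 or N 2 (0.153 and 0.0927), and in urea+N and N under median-of-ratios scaling (0.0532 and 0.0675). In N the call was lost as well with no filter (0.0662), with array weights (0.0599) and with only the compared groups in the model (0.0988). Its family member zma-MIR168b, at 60.8 ± 3.74 TPM in control, had log2 fold changes of -0.65, -0.29 and -0.23 in urea, urea+N and N. Their adjusted p by limma was 0.0402, 0.274 and 0.444. The call in urea was lost without control 1, control 2, control 3, urea 2 or urea 3. The nutrient-responsive families among the microRNA precursors had 6 tested members and 0 calls by limma, with 0, 4 and 1 at an unadjusted p under 0.05 in urea, urea+N and N. As a group they had an adjusted p of 0.130 in urea+N, and 0.0350 with no filter, with the filter an adjusted p of 0.479 with an estimated correlation, and their summed TPM was 3.94 to 6.03 in the control, 6.19 to 9.26 in urea, 10.7 to 19.6 in urea+N and 10.0 to 12.8 in N libraries. The members zma-MIR169e and zma-MIR169h had near-identical TPM, such as 2.27 and 2.25 in urea+N 2, so they may not be separate measurements. Their log2 fold changes in urea+N were 0.94 and 0.96, while that of the member zma-MIR408b was -0.70.

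The 9 kernel genes had a summed TPM of at most 0.742 in any library, the 4 beta-expansin and polygalacturonase genes of pollen type were listed at 0 in all 12 libraries. The 74 plastid-encoded genes, which roots also carry, summed to 0.944 to 4.08 TPM. None of these groups had a member that could be tested. Mitochondrion-encoded genes summed to 83.6 to 125 TPM, with 0 of 23 tested members called against control by limma and 1, 1 and 2 at an unadjusted p under 0.05 (adjusted p = 0.985 in urea, 0.975 in urea+N and 0.645 in N). Of the 111 ribosomal RNA genes tested, 1 was higher and 1 lower in urea, 0 higher and 4 lower in urea+N and 1 higher and 1 lower in N (adjusted p = 0.177, 0.126 and 0.2995). Hormone conjugation and signalling had 2 tested members, too few for a test: *CISZOG2*, which rose in urea+N and N, and the growth repressor gene *D8* (Zm00001d033680), at 89.2 ± 3.11 TPM in control, 81.4 ± 3.18 in urea, 77.1 ± 1.37 in urea+N and 77.1 ± 0.953 in N. The calls of *D8* in urea+N and N (adjusted p = 0.0202 and 0.0214) ended under median-of-ratios scaling (0.0962 and 0.0638), with only the compared groups, without control 1 (0.0627 and 0.0665) or control 2 (0.0720 and 0.0767), and without urea+N 2 (0.0624), N 1 or N 3 (0.0755 and 0.0698).

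The library urea+N 3 listed 25806 genes above 0 TPM, against 29289 to 29521 in the others. A threshold that sets low values to 0 is argued against, since 1139 genes of this library lay between 0 and 0.5 TPM (2898 to 3249 in the others), and so is the treatment, since urea+N 1 and urea+N 2 listed at least 29371 genes. Among genes at 1 to 5 TPM, the share listed at 0 was 29.0% in the third with the shortest transcripts and 4.69% in that with the longest, a ratio of 6.19, as fewer distinct RNA fragments would give. The other libraries show such a gradient too, from 5.44% to 6.60% down to 0.353% to 0.957%, so the ratio alone does not single out this library; its excess over their mean was 23.1 and 4.04 percentage points. A loss of distinct fragments may account for it, with a median deviation from the mean of urea+N 1 and urea+N 2 of 0.426 (log2) at 1 to 5 TPM, where urea+N 1 and urea+N 2 deviate from each other by 0.206, but 0.105 and 0.0958 at 100 TPM or more.

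The photosynthesis genes *RBCS* and *PSAH* were higher in each of the 9 fed libraries than in each control library, with *RBCS* at 22.3 TPM or more in fed and 13.7 TPM or less in control libraries. A difference in library scaling is argued against for *RBCS* and *PSAH*, since the median-of-ratios factors of the libraries, 0.964 to 1.03, are too alike to give such changes. The median log2 change of *RBCS*, *PSAH* and *CAB1* in N, which is that of *RBCS*, was 1.40 on the deposited scale. It was 1.43 under median-of-ratios scaling. For *CAB1* the libraries overlapped, with 11.2 TPM as the lowest fed and 11.3 TPM as the highest control value. Shoot tissue in the fed samples might bring such transcripts and stays open: *RCA1* and *PSBQ1*, which are abundant in green leaves, differed by 0.142 TPM together, fed minus control (SE 0.227), while *RBCS* rose by 17.0 TPM, but both are near the floor, with *RCA1* listed at 0 in 8 of the 9 fed libraries. A response of the roots to nitrogen also stays open and was not tested.

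Only tested genes were put in order along the chromosomes, so untested genes may lie between the members of an adjacent pair. In this order, genes called in the same direction in N against control lay next to each other more often than chance gave. There were 299 such adjacent pairs, against a median of 213 and a highest value of 266 in 10000 shuffles among genes of like expression (one-sided permutation p = 0.0001, the smallest they can give), in line with a hypothesis that neighbours respond together. Reads shared by overlapping genes are argued against as the whole cause, since 291 pairs did not overlap (shuffle median 208, highest 261). Reads shared between tandem copies on one strand stay open: on opposite strands there were 122 pairs, above the shuffle median of 100 (one-sided permutation p = 0.0162) but within the highest of 142, and on the same strand 169 against 108. Tandem copies that truly respond alike would give the same excess, and sequences to tell them apart were not used here.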
